A study of Homo sapiens with 2 samples.

How the data were processed

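Cas9 irCLIP-seq was performed in H1-iCas9 cells, a derivative of the established human embryonic stem cell line H1 in which doxycycline induces a FLAG-tagged Cas9. irCLIP is a crosslinking and immunoprecipitation assay in which ultraviolet light joins a protein to the RNA it touches and reverse transcription tends to stop at the joined base, so that the start of a read marks the contact. Per the labels' protocols, cells received 1 µg/ml doxycycline for 24 hours and were crosslinked at 254 nm with 300 mJ/cm2, and Cas9 with its RNA was recovered with an anti-FLAG antibody. The 2 libraries form 1 group, replicate 1 and replicate 2. The labels do not say whether they came from separate cultures, so the spread between them may be technical. No control library and no RNA abundance measurement were analysed here.

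Each deposited file lists the crosslink regions of 1 library with chromosome, start, end, strand and a score, so regions were called per library and not on pooled reads. The deposited score of a region is the sum of the scores of its crosslink sites, as checked on the values to within 0.01, and its scale is not given in the sources used here. Bowtie2 2.3.5, STAR 2.5.2, SAMtools, UMI-tools, deepTools and the build hg38 are named, per the submitters' processing notes, without role or order. The program that called the regions, its threshold and the treatment of reads with several alignments are not given in the sources used here. Single-site scores stopped at 708.396 in both libraries, which was treated as a ceiling. Read counts were not used here, so the depth behind a region is unknown and intervals cover the counting of regions only. Positions were converted to 1-based hg38 coordinates. In replicate 2, 1 region on chromosome M starts before the first base and was kept in the totals.

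Regions were placed in genes through a table of RefSeq gene spans on GRCh38.p14, the same primary assembly as hg38, with 59716 genes on chromosomes 1 to 22, X, Y and M. The table holds spans without strand, exons or sequence. Gene assignment therefore ignored strand and did not separate exons from introns, and the design was followed only as far as that allowed. Placements were made within the whole gene, and regions were classed by the biotype of the gene at their midpoint in the order protein-coding, long noncoding, pseudogene, small RNA, immune segment or other, no gene. The planned analyses of repeat content and of sequence composition need a genome sequence and were not run, so transposable elements are not named. Regions on unplaced sequences, 5 in replicate 1 and 12 in replicate 2, entered the overlap of the libraries but no gene comparison.

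A region was shared when it overlapped a region of the other library by at least 1 base on the same strand. The number shared was compared with 1000 placements in which each region of replicate 1 moved to a random position in the shortest gene that held it, or outside genes on the same chromosome. The number of genes with a region in both libraries was compared with 10000 random draws within biotype class (protein-coding, long noncoding, other) and gene length decile. For 19 gene lists, with 1323 of 1324 members matched to the table, the members with a region in both libraries were compared with 10000 random lists of the same size from the same strata, two-sided, with Benjamini-Hochberg adjustment. The mitochondrial list was taken by chromosome because the table's symbols have no prefix, and the splicing list was limited to protein-coding genes. As an addition, regions were placed at random within annotated genes 1000 times, with shared regions moved together, so that each gene's chance followed its exact length. Classes were compared between libraries by Fisher's exact test, and intervals are exact 95% binomial (Clopper-Pearson). Regions per gene were compared with the number expected from gene length by a one-sided exact Poisson test over all genes with Benjamini-Hochberg adjustment.

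Named genes followed a rule written before the data were examined, together with the lists, tests and most of the other settings. The rule takes the 15 genes with the most shared regions, the 10 shared regions with the highest summed score, up to 4 members of each list with a region in both libraries (or up to 2 with a region in 1 library), and 10 fixed genes. A gene of the splicing list that the rule takes is not reported here. Genes named outside the rule are marked as chosen after their values were seen. The comparison of tRNA genes, the dense runs (chromosome Y left out), the opposite-strand pairs and their distance limits were also chosen after the data were seen. The methods were tested on simulated data in which regions were placed at random within genes for 20 simulated library pairs. Of 1000 planted shared regions, between 1000 and 1001 were counted as shared. A list of 80 genes with 40 planted members was called in 20 of 20 simulations, and smaller planted effects were not tried. Independent gene sets were called as overlapping in 1 of 20. These sets were drawn evenly within the strata that the test matches on, so length differences inside a decile were not tested there. The length-decile matching called the list of long neuronal genes in 20 of 20 simulations without any enrichment, and the other 18 lists in 0 of 360 tests. Alternatives covered the overlap rule, the score threshold, the matching, the background and each library alone. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.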

Results

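Crosslink regions of FLAG-tagged Cas9 were mapped in H1-iCas9 human embryonic stem cells in 2 irCLIP libraries. Replicate 1 held 4204 regions and replicate 2 held 5995. Almost all were a single base, 99.1% in replicate 1 and 99.7% in replicate 2, and the longest spanned 8 bases. The strands were nearly balanced, with 2075 plus-strand and 2129 minus-strand regions in replicate 1 and 2949 and 3046 in replicate 2. The median deposited score was 21.4 in replicate 1 and 21.3 in replicate 2, and 78 and 113 regions held a site at the score ceiling of 708.396. With a single group and no control library, the comparisons are between the libraries and against random positions, and they describe where regions lie rather than how much Cas9 was bound.

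The first comparison asked which regions recurred in both libraries. The same 2474 regions were found in both, which is 58.8% of replicate 1 (95% interval 57.3 to 60.3) and 41.3% of replicate 2 (40.02 to 42.53), and 2443 of them had identical start, end and strand. The region with the highest summed score lay in LOC100420006 on chromosome 2 (131338441 to 131338442, minus strand), with scores of 815 and 1093 in replicates 1 and 2. It was followed by regions at the ceiling in both libraries, including single bases in EIF2B3, a subunit of a translation initiation factor, at 44854025 on chromosome 1, in LHX8, a LIM homeobox transcription factor, at 75132898 on chromosome 1, and in DNM3, a dynamin GTPase, at 172359616 on chromosome 1. LOC105376449 (22442952) and KIAA1217 (23824629) on chromosome 10 held others, and 4 of the 10 highest lay in no annotated gene. In all, 71 regions reached the summed score of the last of these 10, so the order within the ceiling carries no information. All 78 ceiling regions of replicate 1 recurred in replicate 2, and 107 of the 113 of replicate 2 recurred in replicate 1.

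Sharing rose with the score. In replicate 1, 24.0% of the lowest of 4 score groups were shared (21.4 to 26.7), against 95.5% of the highest group (94.1 to 96.7). In replicate 2 the shares were 22.1% (20.2 to 24.1) and 74.4% (72.1 to 76.6). Over the 2332 identical regions below the ceiling the scores of the libraries correlated with a Spearman rho of 0.64 and a Pearson r of 0.63 on the log2 scale. This correlation is across regions, which are not independent replicates. Random placement of the replicate 1 regions within their own genes gave a mean of 0.207 shared regions and at most 3, against 2470 observed on the placed chromosomes (one-sided permutation p = 0.001, the smallest that 1000 placements can give).

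**Figure D1:**
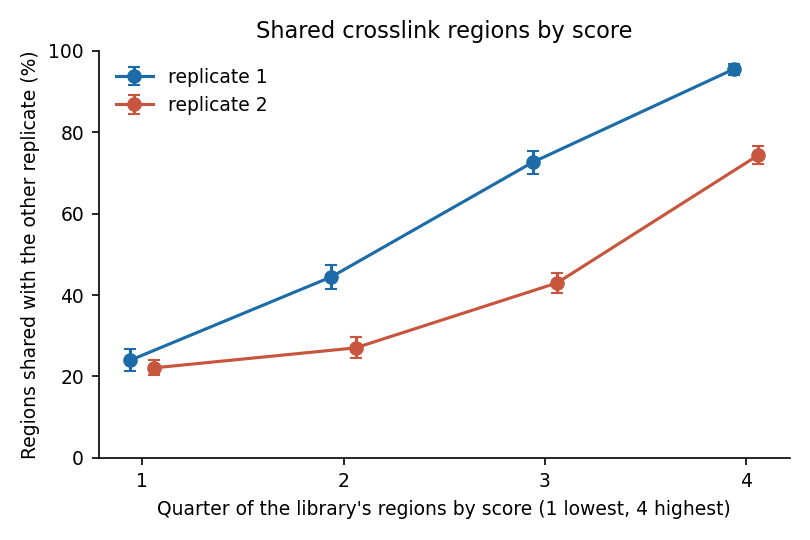
Share of regions found in the other replicate (vertical axis, percent) for 4 groups of a library's regions, cut at the quartiles of its deposited score (horizontal axis), with exact 95% binomial intervals. Sharing goes from 24.0% to 95.5% in replicate 1 and from 22.1% to 74.4% in replicate 2.

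The second comparison asked in which kinds of gene the regions lie. Spans of protein-coding genes held 48.4% ± 1.32 of regions (SD, n = 2), long noncoding genes 12.4% in replicate 1 and 11.9% in replicate 2, and pseudogenes 1.05% and 1.20%. Between genes lay 38.5% of replicate 1 regions (37.06 to 40.02) and 36.7% of replicate 2 regions (35.5 to 38.0). Random positions on whole chromosomes fell in protein-coding spans in 40.7% of cases and between genes in 45.9%. Without gaps between genes of 1 Mb or more, which hold much of the unsequenced part of the chromosomes, these became 44.1% and 41.5%. The share in any gene, 61.5% and 63.3%, exceeded the 58.5% of that setting in both libraries (exact binomial p = 7.9e-05 and 2.95e-14). That test counts regions as independent, although 5.76% and 14.4% of them lay in the opposite-strand pairs described below. It also kept observed regions in gaps of 1 Mb or more and on chromosome M, which the random positions left out. The libraries also had 2474 regions in common, so they are not independent of each other here. Random positions were not limited to sequence where reads can be aligned, so the source of the excess was not tested. Within genes, protein-coding spans took 77.3% and 78.0% of regions, against 75.2% of random positions within genes.

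Regions followed chromosome length. Over 23 chromosomes (1 to 22 and X), the number of regions correlated with length at a Pearson r of 0.98 (Spearman rho 0.98) in replicate 1 and 0.97 (0.96) in replicate 2, each r and rho with a permutation p of 1e-05, the smallest possible, and 2e-05 after Benjamini-Hochberg adjustment over 4 relations. Without the 2 chromosomes farthest from the median length, r was 0.97 and 0.95. Against the number of protein-coding genes, r was 0.58 in replicate 1 (permutation p = 0.003, adjusted 0.003; rho 0.57 with p and adjusted p of 0.0055) and 0.66 in replicate 2 (permutation p = 0.0005, adjusted 0.00067; rho 0.66 with p = 0.00088 and adjusted p = 0.0012). It fell to 0.41 and 0.54 without the 2 extreme chromosomes. Chromosome 19, dense in genes, was chosen after its values were seen. It held 1.45 regions per Mb in replicate 1, close to the 1.40 of chromosome 20, and 3.02 in replicate 2. Its share of regions was 2.02% (1.62 to 2.49) and 2.95% (2.54 to 3.41), a difference between these libraries at a Fisher's exact p of 0.0034, unadjusted among 23 chromosomes.

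Genes of the small RNA class, which also takes ribosomal and miscellaneous RNA genes of any length, separated the libraries. They held 2 regions of replicate 1 (0.0476%, 0.00577 to 0.172) and 28 of replicate 2 (0.468%, 0.311 to 0.676), and this class alone passed the comparison of the 6 classes (Fisher's exact test, adjusted p = 0.000264, with the adjusted p of the other classes at 0.128 or above). The class includes MROH5, a gene of 73405 bases named after its values were seen, which 1 region of each library overlapped. By any overlap, 27 tRNA genes held 1 region each in replicate 2 and 1 tRNA gene held 1 in replicate 1 (Fisher's exact p = 8.52e-06), a class compared after the data were seen. At or above each library's median score the numbers were 13 and 1 (Fisher's exact p = 0.0114). The total length of the 465 tRNA genes, 34.8 kb, would give 0.0675 regions in replicate 2 by chance. The highest scores in replicate 2 were those of TRP-CGG2-1 (a proline tRNA, 215.6), TRR-TCT1-1 (an arginine tRNA, 175.2) and TRT-TGT2-1 (a threonine tRNA, 146.5). TRT-TGT2-1, on chromosome 1 from 222465005 to 222465077, was the gene also hit in replicate 1, with a score of 21.4 at the neighbouring base. Of the 27 genes, 16 lay on chromosome 6. In 20 of the 21 tRNA genes of at most 74 bases the site lay between bases 36 and 44, counted from the gene edge upstream on the strand of the region, and in TRD-GTC2-7 at base 53. In the 6 genes of 85 to 108 bases it lay between bases 52 and 74. These tests compare the libraries and not conditions.

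**Figure D2:**
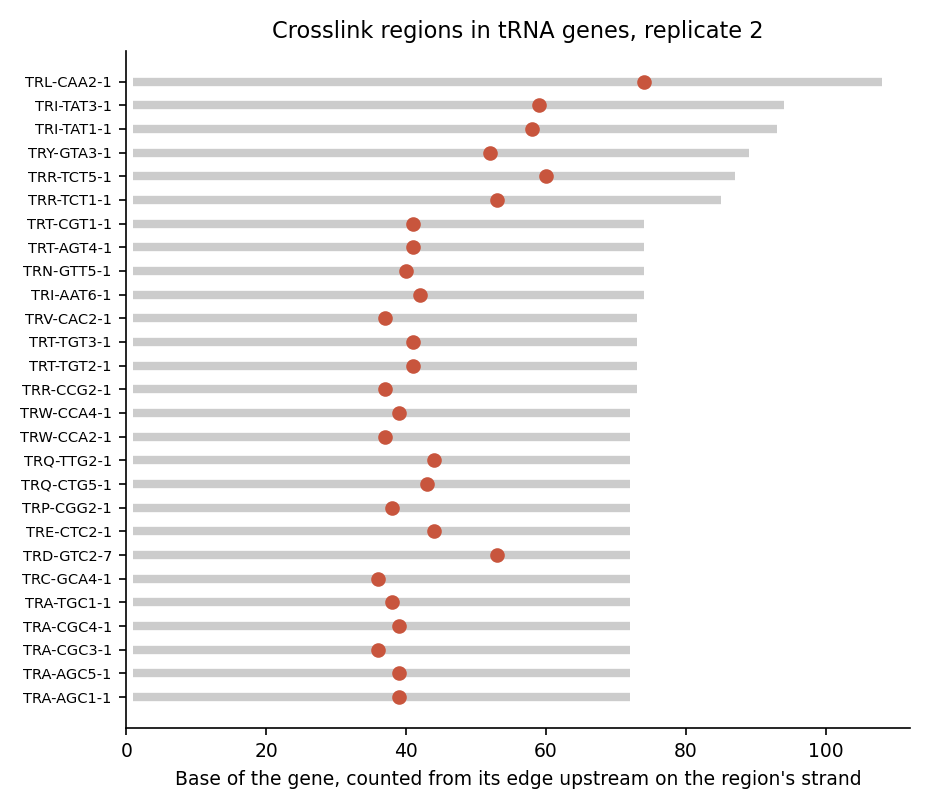
Position of the crosslink region (points) within each of 27 tRNA genes in replicate 2 (grey bars, gene length in bases), counted from the gene edge upstream on the strand of the region. In genes of at most 74 bases the sites lie between bases 36 and 44, except at base 53 in TRD-GTC2-7.

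Other noncoding classes held few regions, and their short genes gave few by length. No region lay in any of the 43 small structured RNAs matched, where placement by length gave 0.003 members hit in both libraries, among them RN7SK, a regulator of transcription elongation, and RN7SL1 and RN7SL2, the signal recognition particle RNA. Of 573 snoRNAs and scaRNAs, which guide RNA modification, SNORD17 alone held a region, in replicate 2, and placement gave 0.063 members hit in both libraries, with 0 observed. No snRNA, vault RNA or Y RNA gene held one. In replicate 2, 3 ribosomal RNA genes held regions, RNA45SN2, RNA45SN3 and RNA28SN3, the last nested in RNA45SN3 and sharing its region, and replicate 1 had 0. Replicate 2 had 7 miRNA genes with a region, among them MIR15A, MIR155, MIR4454 and MIR548AW. Replicate 1 had MIR548AW alone, at 132945718 on the plus strand, next to a replicate 2 site at 132945719. The miRNAs and ribosomal RNAs named here were chosen after their values were seen. On chromosome M, replicate 2 had 3 regions, with 1 in COX1 and 1 in COX2, subunits of cytochrome c oxidase, where their lengths gave 0.00348 and 0.00154, and replicate 1 had 0. Members of multicopy families share near-identical sequence, and the handling of such reads is not given in the sources used here, which also limits what an empty class shows.

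The third comparison asked which genes held regions in both libraries, whatever the strand of the gene. At least 1 region lay in 2314 genes in replicate 1 and in 3169 in replicate 2, and 1624 genes were common to both. Draws matched on biotype class and length decile gave 524 common genes (central 95% range 493 to 556, one-sided permutation p = 0.0001, the smallest possible), and independent sets would give 122.8. These draws did not keep shared regions together, so most of this excess restates that the same regions recurred. When the regions were placed at random within genes with shared regions kept together, 1662 common genes were obtained (1620 to 1705, permutation p = 1.0), a comparison in which the shared regions fix most of the overlap. Regions without a counterpart within 100 bases in the other library had 189 common genes, against 151 in draws matched on length decile (131 to 171, permutation p = 0.0002) and 225.5 by placement on exact length (200 to 250), which was higher than observed (two-sided permutation p = 0.008). Long genes were hit most. Among protein-coding genes of the longest decile, with a median of 249.6 kb, 28.7% had a region in both libraries, against 0.449% of the shortest decile.

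The genes with the most shared regions were long genes and immunoglobulin loci. IGH, the immunoglobulin heavy chain locus (chromosome 14, 105586437 to 106879844), had 11 regions in each library, 10 of them shared, and IGK and IGL, the light chain loci, each had 4 shared. MACROD2, an ADP-ribose hydrolase gene of 2057682 bases, had 6 regions in replicate 1 and 10 in replicate 2, with 5 shared, where its length gave 3.17 and 4.64. CNTNAP2, a neurexin-family adhesion gene, had 6 and 6, against 3.55 and 5.20 from its length, and PTPRD, a receptor tyrosine phosphatase, had 6 and 7, against 3.54 and 5.19. ARHGAP15, CPVL, TMTC2 and ZFHX3 also had 4 shared regions. ADCY2, ASIC2, AUTS2, BIRC6 and CAMTA1 had 3, and were taken by the naming rule from 27 genes with that number. None of these genes other than IGH in replicate 1 (adjusted p = 0.0315) exceeded its length-based expectation after adjustment in the exact Poisson test. IGH had an adjusted p of 0.165 in replicate 2.

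Over all genes, 15 in replicate 1 and 22 in replicate 2 held more regions than their length gave (exact Poisson test, Benjamini-Hochberg adjusted), with 11 in common, all named here after their values were seen. Immunoglobulin segments made up 9 of them, namely IGHG2, IGHG4, IGHV1-3, IGHV3-35, IGHV3OR16-8, IGKJ4, IGKV1-6, IGLC1 and IGLC6, and the others were CSH2, a placental hormone gene, and EIF5AP2. Each of the 11 held a pair of regions on opposite strands in both libraries. The Poisson test treats the members of such a pair as independent.

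In replicate 2 several protein-coding genes lay in dense runs on a single strand, chosen after the data were seen as at least 10 same-strand regions within 500 kb. Runs were sought in replicate 2 only, and replicate 1 was counted within them. PLCB1, a phospholipase C gene, held 12 regions in replicate 2, as against 1.70 expected from length (exact Poisson test, adjusted p = 0.00177), and 2 in replicate 1. Its run extended into PLCB4, with 17 minus-strand regions over 426 kb of chromosome 20 and 0 on the plus strand. MAPK10, a stress-activated kinase gene, held 12 regions against 1.32 expected (exact Poisson test, adjusted p = 0.000253), also with 2 in replicate 1, in a run of 14 plus-strand regions that began in ARHGAP24, with 1 minus-strand region. ABCB4, a phospholipid transporter gene, and the overlapping CROT, a peroxisomal acyltransferase gene, held 8 and 5 regions against 0.249 and 0.122 expected (exact Poisson test, adjusted p = 1.73e-05 and 0.00177) in a run of 12. Replicate 1 had 3, 2 and 3 same-strand regions in these runs. The highest score of each run lay at or near its downstream end, with 16, 12 and 11 regions upstream of it and 0, 1 and 0 downstream. Upstream and downstream follow the strand of the regions. Whether a run lies on the strand of its genes was not examined.

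**Figure D3:**
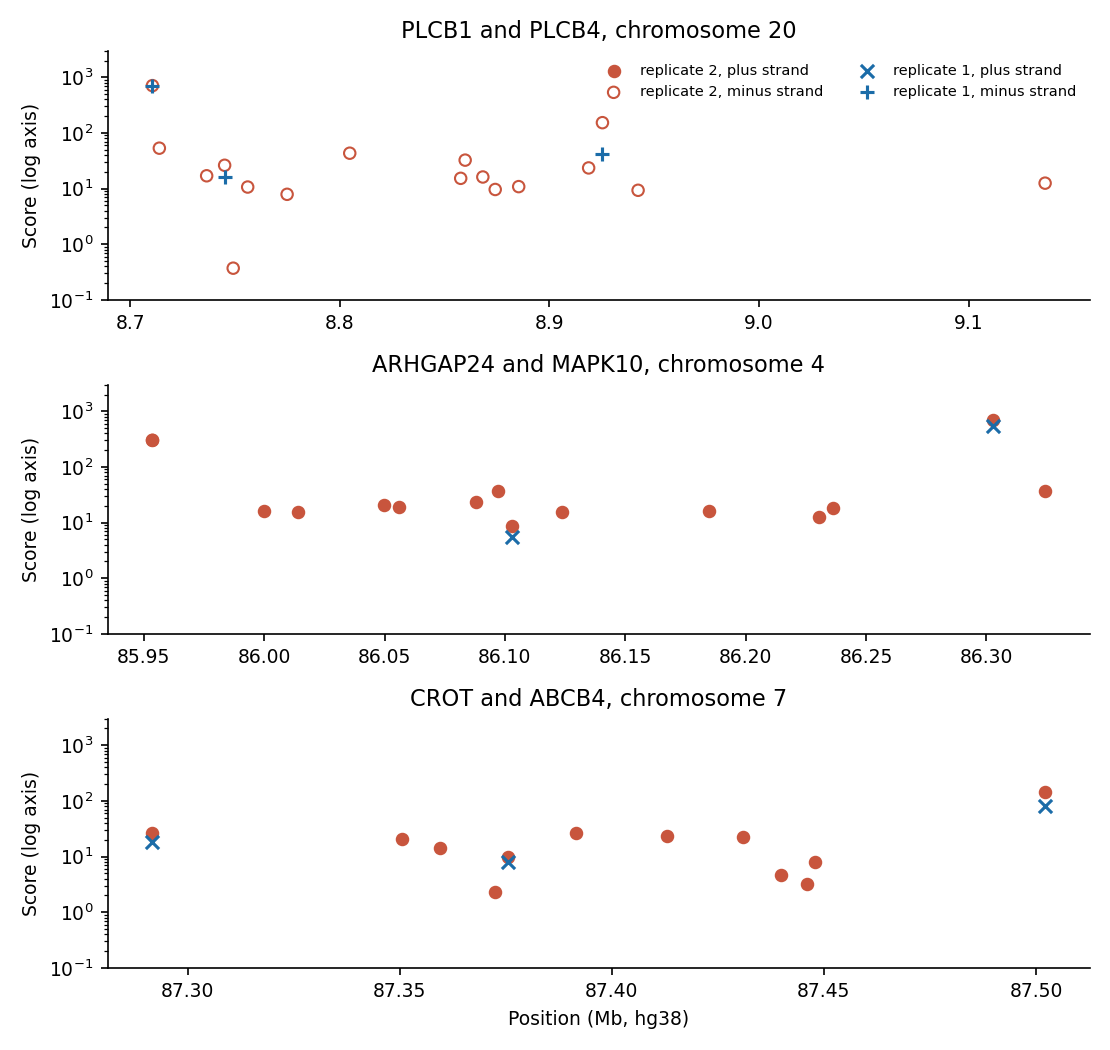
Crosslink regions along the 3 dense runs, with position on hg38 in Mb (horizontal axis) and deposited score (vertical log axis); circles are replicate 2 and crosses replicate 1, with strand by symbol. Replicate 2 has 17, 14 and 12 same-strand regions in the runs and replicate 1 has 3, 2 and 3.

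The fourth comparison asked whether particular gene groups, among them neural and pluripotency genes, held regions more often than their size predicts. Of the 19 lists, the 48 long neuronal adhesion and guidance genes stood apart under the length-decile matching, with 39 members hit in both libraries against 13.6 in matched lists (8 to 20, adjusted permutation p = 0.0038). These genes have a median length of 1161 kb, against a median of 249.6 kb for all protein-coding genes of the longest decile. Placement by exact length gave 35.2 members (29 to 40, adjusted permutation p = 1.0), and simulated regions without enrichment gave the same call under the decile matching in 20 of 20 cases. Under placement 0 of the 19 lists were called. MACROD2, PTPRD, CNTNAP2 and CSMD1, a complement-regulatory gene, led the list, and AUTS2 was among its members.

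The 80 neurodevelopmental disorder genes held 9 members hit in both libraries, against 13.0 in matched lists (7 to 19, adjusted permutation p = 1.0) and 12.3 by placement. GRIN2B, an NMDA receptor subunit, ANK2, an ankyrin, FOXP1, a forkhead transcription factor, and DYRK1A, a protein kinase, each had 2 shared regions. Of 29 neural lineage markers, HESX1, a homeobox gene of the forebrain, was hit in both libraries, against 1.24 in matched lists. Of 23 mesoderm and endoderm markers, 0 were hit in both, and KDR and MESP1 were hit in replicate 2.

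Pluripotency genes held few regions, and their lengths gave few. Of 32, 0 were hit in both libraries, against 1.11 in matched lists (0 to 3, adjusted permutation p = 1.0), so a lower count than expected could not have been detected. L1TD1 held 1 region in replicate 2 and LIN28B held 1 in replicate 1. POU5F1 and LIN28A, core factors of this cell type, held none, and neither did the stem cell transcripts ESRG and LINC-ROR. The length of each of these genes gave at most 0.0427 regions in either library. LINC01194 was hit in both libraries in the list of 20 stem cell and TE-derived transcripts, which had 0.442 in matched lists.

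No list of genes of abundant RNAs was called as hit more or less often than matched lists. Of 86 ribosomal protein genes, 0 were hit in both libraries and 2 in replicate 2 (RPL24 and RPL39L), and of 29 translation factors EIF3A was hit, in replicate 2. None of the 69 replication-dependent histone genes was hit. MALAT1 and NEAT1, abundant nuclear RNAs, held none. Of 23 listed long noncoding RNAs, 3 were hit in both libraries, namely PVT1, LINC01876 and LINC-PINT, against 1.60 in matched lists and 2.72 by placement. Members hit in both libraries in the remaining lists included HNRNPA2B1 of 65 splicing and hnRNP genes, KRT8 of 27 cytoskeleton and glycolysis genes, FKBP4 of 26 chaperones, SNHG1 of 39 snoRNA host genes, FAS, DDB2 and PRKDC of 30 p53 and DNA damage response genes, and MBP of 44 other-tissue markers. All of these lists had an adjusted permutation p of 1.0. Matched lists had at most 1.60 members hit on average in these groups, so lower counts than expected could not have been detected.

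**Figure D4:**
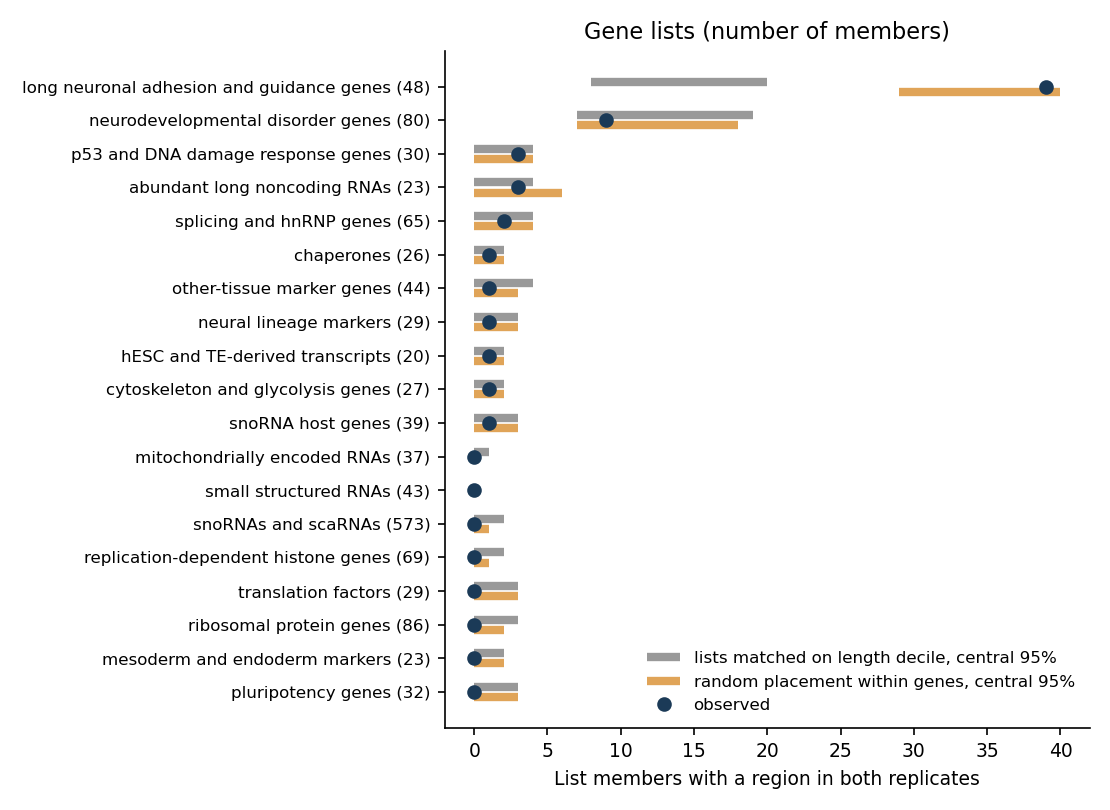
Members with a region in both replicates (points, horizontal axis) for each of 19 gene lists, with list size in parentheses and the central 95% range of lists matched on length decile (grey) and of random placement within genes (orange). The long neuronal list, at 39, lies above the grey range of 8 to 20 and inside the orange range of 29 to 40.

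Regions on opposite strands lay close together far more often than after a shift of the strands against each other. Within 110 bases, a distance set after seeing the data, replicate 1 had 121 such pairs and replicate 2 had 432, which involved 5.76% and 14.4% of regions, whereas shifting the minus strand by 10 kb left 1 and 0 pairs. In all 121 and all 432 pairs the plus-strand region was on the left. Within 300 bases, 121 pairs had it on the left and 1 on the right in replicate 1, and 435 and 2 in replicate 2. The distance had a median of 25 bases in both libraries, with quartiles of 22 and 30, and 114 and 421 pairs were at most 45 bases apart. In each library 7 of the wider pairs lay in immunoglobulin genes. Among the genes named above by rule or as runs, IGH held 4 pairs in each library and IGK and IGL held 2, and MACROD2, PTPRD, LINC01194, GRIN2B, RPL24, PVT1 and ARHGAP24 held 1 in replicate 2, where both regions of RPL24 formed the pair. Regions in pairs were shared between the libraries in 89.7% of cases in replicate 1, against 56.97% of the other regions, and in 28.5% of cases in replicate 2, against 43.4%.

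**Figure D5:**
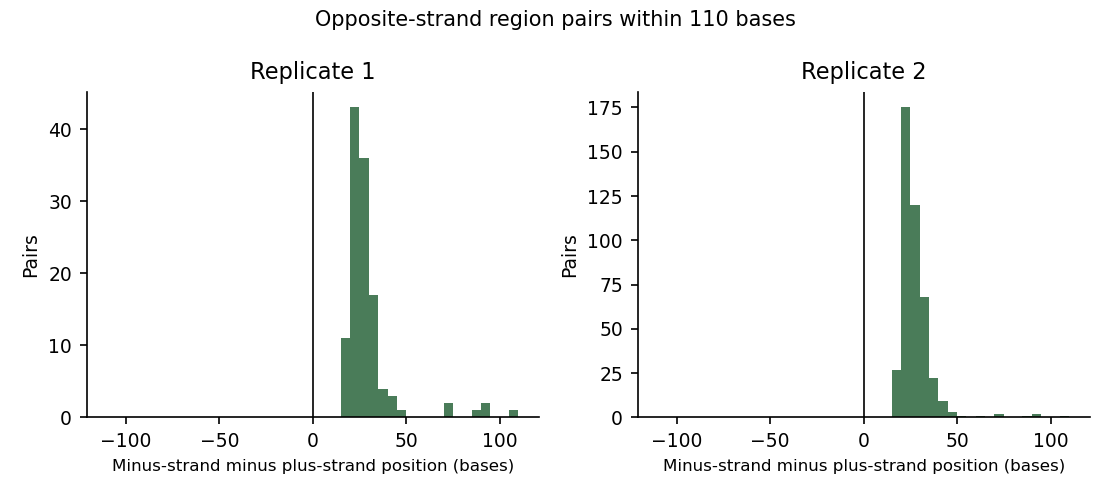
Distance in bases from the plus-strand to the minus-strand region (horizontal axis) for all opposite-strand pairs within 110 bases, with the number of pairs on the vertical axis. All pairs lie to the right of 0, with a median of 25 bases in both replicates.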

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

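Regions on unplaced or unlocalized sequences, which the gene comparisons do not use, numbered 5 in replicate 1 and 12 in replicate 2. Both counts passed the flagging limit of 3, the upper limit for a count of 0, which is not a test for excess. The number expected from the length of these sequences was not computed, and 4 regions had the same position and strand in both libraries.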

How the results depend on the processing

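The share of replicate 1 regions found in replicate 2 stayed between 55.8% and 69.2% under the overlap, strand, distance, score, chromosome and pair alternatives, and was 41.3% with replicate 2 as the query, each time above every placement, except that a required overlap of 50% of both regions (58.5%) was given no placements of its own. The protein-coding share was 47.5% to 49.4% with each library left out in turn and moved by less than the spread between libraries under the others. Common genes numbered 1624 and fell to 930 at or above the median score, which leaves fewer regions, and to 189 for regions without a counterpart within 100 bases in the other library, added after seeing the data, where matched draws gave 151 (131 to 171, permutation p = 0.0002) and placement on exact length, also added, gave 225.5 (200 to 250), more than observed (two-sided permutation p = 0.008). Without opposite-strand pairs and runs the number was 166, against 189.2 (167 to 212, two-sided permutation p = 0.042); the cause was not tested. Random placement of all regions, also added later, kept the 1624 and ended the call (permutation p = 1.0), which moving the shared regions together largely fixes. The same placement left 0 of 19 lists called where the length-decile matching called 1. The called list was the same under the 6 other alternatives, the libraries left out in turn included, and the simulation without enrichment called it too, so that matching does not control its length. Regions in tRNA genes of replicate 2 numbered 13 at or above the median score, against 1 in replicate 1 (Fisher's exact p = 0.0114). Settings that need exons, exonic length, gene parts, repeats or sequence were not run because the annotation used here has none of these, and placement anywhere in the gene became the main setting. No paired analysis was possible because the study has 1 group. The depth of the libraries is unknown, and a region missing from 1 library was not shown to be absent there.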

Other observations

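The tests of which strand lies on the left, of ceiling sites near the CROT and ABCB4 run and of regions without a counterpart were chosen only after the result was seen, as were all 3 patterns weighed here, the placement by exact length and the values without runs and opposite-strand pairs, whereas the bounds of the other tests were written before their results. Beyond the runs already described, the CPVL gene, which encodes a carboxypeptidase, held 5 regions in replicate 1 and 4 in replicate 2 within 200816 bases, with 4 shared, against 0.309 and 0.453 expected from its length (exact Poisson test, adjusted p = 0.057 and 0.538). PVT1, a long noncoding RNA gene next to MYC, held 2 and 6, with 0.472 and 0.692 expected (exact Poisson test, adjusted p = 1.0 and 0.151). RPL24, a ribosomal protein gene, held 2 regions in replicate 2, which formed an opposite-strand pair, and 0 in replicate 1.

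The opposite-strand pairs were the most regular pattern. If independent RNAs from both strands of a locus gave rise to them, the plus-strand region should lie on the left about as often as on the right, but it did so in 100% of the 432 pairs of replicate 2 (exact 95% interval from 99.2), which argues against that source. If a pair marks the 2 ends of one short aligned stretch, read from either strand, the scores of its members should rise together, and they did in replicate 2 (Spearman rho 0.55, permutation p = 0.0001, the smallest possible), while in replicate 1 rho was 0.14 (p = 0.054). A stretch of this kind may be a short duplex RNA, DNA in the library, or a partial alignment of reads from elsewhere, and these stay open because reads and genome sequence were not used here. With a single group, no biological explanation that rests on a comparison of conditions was tested.

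The dense runs of PLCB1, MAPK10 and ABCB4 in replicate 2 ended near their highest-scoring region. A candidate explanation is split alignments, in which one part of a read from a ceiling site is placed far upstream on the same strand. The CROT and ABCB4 run had 0 same-strand ceiling sites in it or within 500 kb (its highest score was 143). This argues against an anchor at the ceiling there. An anchor below the ceiling was not tested, and that run too had 11 regions upstream of its highest score and 0 downstream. For the runs of PLCB1 and MAPK10, split alignments from a ceiling site were tested elsewhere, at the 111 ceiling sites of replicate 2 outside the runs. There, 74 same-strand regions within 500 kb lay upstream and 57 downstream, leaving out other ceiling sites and distances up to 110 bases. This is 56.5% upstream (47.6 to 65.1, exact binomial p = 0.162). The interval holds both 50% and 60%, so this test leaves the explanation undecided for these runs. On the opposite strand the upstream share was 43.5% (34.26 to 53.04). At the 78 ceiling sites of replicate 1, 37 same-strand regions lay upstream and 42 downstream, which is 46.8% upstream (35.5 to 58.4, exact binomial p = 0.653). Transcription through the loci in the cells of replicate 2 stays open as well and was not tested, because the gene table has no strand.

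Long genes were hit most often, which could come from transcripts of those genes or from placement by length alone. Transcripts of the host gene should put neighbouring regions of a protein-coding gene on the same strand, in at least 75% of cases by the bound set beforehand. In replicate 2 this held for 38.9% of 718 neighbouring pairs (35.3 to 42.5), and without the runs and opposite-strand pairs for 51.8% of 423 (46.9 to 56.6); in replicate 1, without such pairs, it held for 50% of 316 (44.4 to 55.6). These values argue against host-gene transcripts as the main source. For the long neuronal list, placement by length alone was not excluded, since 39 members were hit against a range of 29 to 40. Regions without a counterpart had 189 common genes, below the range of 200 to 250 (two-sided permutation p = 0.008). That placement, however, hit 2075 genes in replicate 2, against 1961 observed. Without opposite-strand pairs and runs the number was 166, against 167 to 212 (two-sided permutation p = 0.042). There the placement hit 996.4 genes in replicate 1 and 1705 in replicate 2, against 990 and 1770 observed. A surplus of genes hit in replicate 2 therefore does not account for the lower number there. The comparison of regions without a counterpart, chosen after the result was seen, does not settle whether length is the whole account. In addition, 2443 regions recurred at the same position, which placement by length alone does not give. Their recurrence does not show why long genes were hit.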
